A study of Mus musculus with 41 samples.

How the data were processed

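Gene expression was measured by bulk RNA sequencing of whole mouse endometriosis lesions, with 41 libraries in 11 groups. Per the labels' protocols, a uterine punch of 4 mm was glued to the inner wall of the peritoneal cavity of a recipient mouse, the mice were 12 to 16 weeks old, and from day 7 each received 3 injections of PBS or of 1 µg IL-33 into the peritoneal cavity over 6 days. ILC2s (120000 or 250000 cells) were given by the same route on the day before IL-33. For lesion transfer, fragments of each genotype were placed in recipients of the other, and the genotype in the labels is that of the fragment. The recipients of all other lesions were taken to have the genotype of the fragment. Per the labels' protocols, RNA came from snap-frozen lesions (Norgen kit) and libraries were made with the NEBNext UltraExpress RNA kit. Groups and replicate numbers were taken from the sample titles and characteristics. The labels do not state that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

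The values used were the raw counts per gene deposited by the authors, in 1 table of 21249 genes. Per the submitters' processing notes, the tools were Trimmomatic, STAR, HTSeq, edgeR and limma with the genome build GRCm38, with no versions, order or strand setting. The annotation is not given in the sources used here. The lowest gene total over the 41 libraries was 411 counts, a mean of 10.0 per library, so genes with low counts had been left out by a rule that is not stated, and genes switched off in most groups may be missing from every test. Without a known strand setting, overlapping and antisense genes cannot be separated. Genes with near-identical relatives, among them Chil3 and Chil4, Ear2 and Rnase2a, the Sprr2 family, haemoglobins and immunoglobulin genes, are uncertain because reads can be shared or lost among them. Symbols were placed on GRCm38 with GENCODE M21, where 20775 of the 21249 had a unique position and 42 had more than 1.

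Library totals were 28.9 to 70.5 mega-counts (median 42.9), which sets the counting error of genes with few counts. No batch or date is labelled. Library names fall in runs of numbers that follow the groups in part: the IL-33-treated Cre-control and deficient libraries interleave, as do the group with added PBS and the group given 250000 ILC2s, while both wild-type groups, the floxed controls, the PBS group, the deficient group given 120000 ILC2s and each lesion-transfer group have a run of their own. Apart from deficient lesions against Cre controls and 250000 ILC2s against added PBS, groups compared therefore lie in different runs, and a difference between runs cannot be told apart from one between groups. None of the 58 pairs of libraries within a group held counts alike within sampling noise (chi-square per degree of freedom 19.7 to 1314).

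Differential expression was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, robust dispersions, quasi-likelihood F-test, two-sided) in 1 model of 11 group means over all 41 libraries, with a contrast per comparison and Benjamini-Hochberg adjustment at 0.05. All groups shared the estimate of spread because several groups are small, and the biological coefficient of variation was 0.465. The filterByExpr rule removed no gene. A standard error is the absolute log2 fold change divided by the square root of F. The 12 comparisons were deficient against the mean of the 3 competent genotypes, IL-33 against PBS, 3 ILC2 transfers, recipient genotype, fragment genotype, Cre against floxed controls, wild type against both, added PBS, and 2 interactions between transfers. The transferred lesions alone served as the target of gene sets. Log2 CPM used a prior count of 2, and a list score is the mean log2 CPM of the list's measured members. For genes with 1 to 3 counts in a group, the ratio has an exact 95% Poisson interval that covers counting error only.

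Before the data were examined, 28 gene lists with 366 entries (360 distinct genes) were fixed: ILC2, type 2 response, eosinophil, macrophage and monocyte, resident peritoneal macrophage, neutrophil, mast cell and basophil, T cell, regulatory T cell, B cell and plasma cell, NK and cytotoxic, dendritic cell, extracellular matrix and fibroblast, endothelium and angiogenesis, endometrial epithelium, endometrial stroma, estrogen response of the uterus, smooth muscle, skeletal muscle, adipocyte, mesothelium, interferon response, type 17 and acute inflammation, proliferation, nerve and Schwann cell, immediate early and stress, blood, and mitochondrial transcripts. Il5 and Il13 stand in both the ILC2 and type 2 lists, Il2ra in the ILC2 and regulatory T cell lists, and Ltf, Muc1 and Pgr in the estrogen list and another. Of the members 17 were not analysed here, among them Areg, Epx, Il4, Ifng and Il17a. Lists were tested with camera (limma 3.58.1) on voom values at an inter-gene correlation of 0.01 and again with a correlation estimated from the data, adjusted over the 28 lists. Sets of the 100 genes with the smallest p per direction from one comparison were tested in comparisons that share none of its libraries. The comparisons, these tests and the rule for named genes were also fixed before the data were examined. That rule took the 6 largest log2 fold changes per direction among genes that passed with a mean log2 CPM of at least 1, leaving out predicted genes and pseudogene symbols, or the 3 smallest p-values per direction where none passed. It also took the 3 smallest p-values within each list that camera called, and a panel of 18 genes, all of them for deficient against competent lesions and those that passed elsewhere. Some genes that did not pass are left out here. One gene that this rule takes in the transferred lesions is not reported here.

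Alternatives fixed in advance were the scaling of DESeq2 in edgeR, no filter, DESeq2 1.42.0, limma with quality weights, fits to the compared groups alone without and with the replicate number as a block, the skeletal muscle score as a covariate, other comparison groups, each replicate left out in turn, and the estimated correlation. Added after seeing the data were fits without the 4 libraries with liver transcripts (Alb above a log2 CPM of 12), with muscle and epithelium scores or with muscle, epithelium and liver scores as covariates, among genes with a mean CPM of at least 1, the transferred lesions alone for recipient and fragment genotype, and 250000 ILC2s against the IL-33 group in fits to both groups without and with the replicate number as a block, and 1 control for both transfers in the difference between 250000 and 120000 ILC2s, as was the list of 14 liver genes. Whether replicate numbers pair libraries was checked by correlating, over genes, the deviations of same-numbered libraries from their group means. All 4 pairs of the IL-33 group and the group given 250000 ILC2s, which meet in the difference between 250000 and 120000 ILC2s and in an alternative, exceeded 0.1 (0.33 to 0.53; 7 of 8 libraries correlated best with their own number), as happened in 4 of 45 pairs of groups. The main procedure was tested on simulated counts. For deficient against competent lesions it recovered 46.3%, 74.6% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold among 21249, with 8 false calls. For 250000 ILC2s it recovered 28.4%, 59.7% and 86.4% (5 false calls), and for 120000 in deficient mice (2 libraries) 5.97%, 38.8% and 72.7% (1). Few counts and tissue mixture were not tested apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.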

Results

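Gene counts were analysed from 41 mouse lesion libraries in 11 groups, made in a transplantation model of endometriosis, the growth of uterine lining tissue outside the uterus. The design varied the presence of group 2 innate lymphoid cells (ILC2s), a source of type 2 cytokines, and interleukin-33 (IL-33), which activates them. IL-33 was given to wild-type C57Bl/6J mice, to mice with floxed Id2 alleles (floxed controls) and to mice with the Nmur1-driven Cre (Cre controls), all ILC2-competent by the series' design. Mice with both were its ILC2-deficient genotype, and each of these groups had n = 4. Further deficient groups received PBS alone, IL-33 with added PBS or IL-33 after transfer of 250000 ILC2s (n = 4 each). Transfer of 120000 ILC2s before IL-33 was made in deficient (n = 2) and wild-type mice (n = 3). In the lesion-transfer groups, Cre-control fragments grew in deficient recipients (n = 4) and deficient fragments in Cre-control recipients (n = 4), both with IL-33. Library totals in mega-counts (M) were 36.8 to 45.6 M in wild type, 38.5 to 49.5 M in floxed controls, 31.8 to 44.1 M in Cre controls and 30.4 to 43.0 M in the IL-33-treated deficient group. With PBS alone they were 41.1 to 70.5 M, with added PBS 39.4 to 45.4 M and after 250000 ILC2s 28.9 to 46.4 M. After 120000 ILC2s they were 46.6 to 51.5 M in deficient and 42.9 to 58.5 M in wild-type mice. Cre fragments in deficient recipients had 28.9 to 48.1 M and deficient fragments in Cre recipients 37.9 to 41.2 M. Fold changes are given as log2 values ± standard error, levels as CPM (counts scaled to a common library total) ± SD.

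The lesions differed in the tissue they held. A list of 14 liver genes, drawn up after the values were seen, took 3.10% to 11.7% of the counts in 4 libraries, which were replicate 4 of the wild-type group, replicate 3 of the Cre controls, replicate 2 of the IL-33-treated deficient group and replicate 3 of the wild-type group given 120000 ILC2s. In the other 37 libraries it took at most 0.0993%. Albumin (Alb) averaged 44462 CPM in those 4 libraries and 20.2 CPM in the others. The 16 skeletal muscle genes took between 0.0117% and 17.8%, with the lowest shares in replicate 1 of the deficient group given 120000 ILC2s (0.0117%), replicate 4 of the group given 250000 ILC2s (0.0123%) and replicate 3 of the Cre controls (0.0131%).

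**Figure D1:**
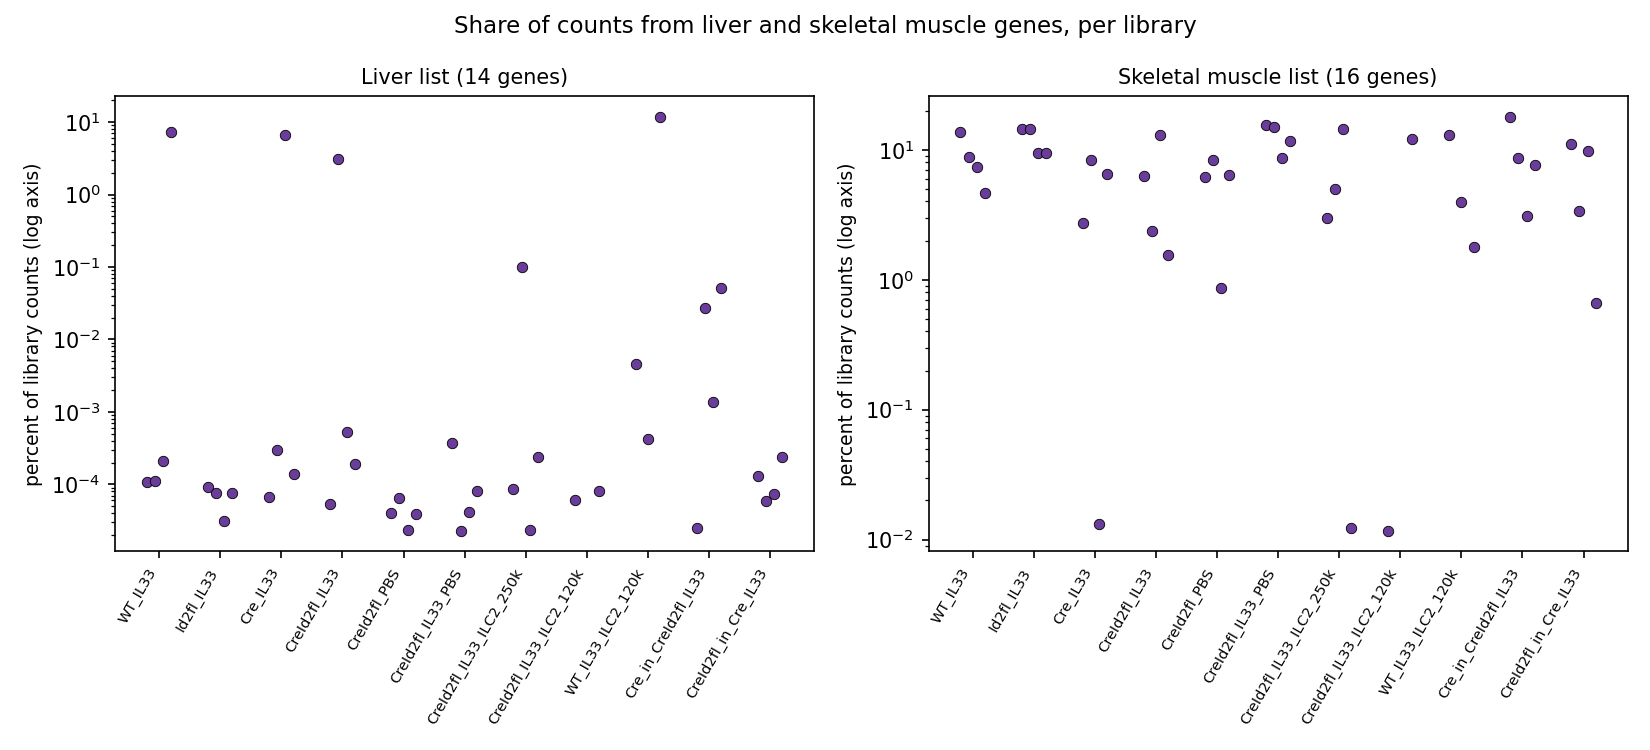
Share of each library's counts, in percent on a log axis, that came from 14 liver genes (left) and 16 skeletal muscle genes (right); each point is a library, and group names join genotype (WT wild type, Id2fl floxed controls, Cre Cre controls, CreId2fl deficient), treatment and ILC2 number, with A_in_B for a fragment of genotype A in a recipient of genotype B. In 4 libraries the liver share lay between 3.10% and 11.7%, against at most 0.0993% in the others, and the muscle share spanned 0.0117% to 17.8%.

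Id2, the gene targeted in the deficient line, encodes a transcriptional regulator required for innate lymphoid cells and lies on chromosome 12 from 25093799 to 25097140 (GRCm38, GENCODE M21, protein-coding, minus strand). Under IL-33 its level was 43.2 ± 14.3 CPM in wild type, 44.2 ± 4.38 in floxed controls, 44.2 ± 13.1 in Cre controls and 48.1 ± 8.51 in deficient lesions (SD, n = 4 each). It was 56.0 ± 18.2 CPM in deficient lesions given PBS, 46.6 ± 7.84 with IL-33 and added PBS and 59.5 ± 12.8 after 250000 ILC2s (n = 4 each). The Cre fragments in deficient recipients had 45.4 ± 11.6 CPM and the deficient fragments in Cre recipients 38.3 ± 7.25 (n = 4 each). Both deficient libraries given 120000 ILC2s held 60.5 and 42.4 CPM, and the 3 wild-type ones 28.9, 48.0 and 73.4. Id2 did not differ between deficient and competent lesions (0.13 ± 0.21, adjusted p = 0.741). Only cells that use the Cre driver would lose the gene, so its level in whole lesions does not check the deletion.

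The first comparison asked how IL-33-treated lesions of ILC2-deficient mice differ from those of the 3 competent genotypes (n = 4 against 12). The cytokine genes Il5 (chromosome 11, 53720794 to 53725106) and Il13 (chromosome 11, 53631324 to 53634702), main products of ILC2s, were lower in deficient lesions, 17.4-fold (log2 −4.12 ± 0.54, adjusted p = 1.99e-05) and 23.7-fold (−4.57 ± 0.57, adjusted p = 1.14e-05). Chil3 (chromosome 3, 106147554 to 106167564), a chitinase-like protein of alternatively activated macrophages, was 44-fold lower (−5.46 ± 1.04, adjusted p = 0.00106). It stood at 44.5 ± 28.1 CPM in deficient lesions against 2928 ± 1214 in Cre controls, 2563 ± 949 in wild type and 1006 ± 330 in floxed controls (n = 4 each). Retnla (chromosome 16, 48842551 to 48844461), a resistin-like protein of the same cells, was 13.3-fold lower (−3.73 ± 0.79, adjusted p = 0.00274). The chemokine gene Ccl17 was 16.9-fold lower (−4.08 ± 0.61, adjusted p = 0.000108). The eosinophil ribonuclease genes Rnase2a and Ear2 were 21.5-fold and 8.16-fold lower (−4.43 ± 0.78, adjusted p = 0.000535, and −3.03 ± 0.36, adjusted p = 7.26e-06). Of the 16 measured genes of the fixed panel, 6 (Il5, Il13, Chil3, Retnla, Gata3 and Klrg1) had all 4 deficient libraries below all 12 competent ones, which random assignment of the libraries gives a gene in 0.110% of cases in either direction. Chil3 and Chil4, and Ear2 and Rnase2a, have close relatives whose reads the counting could have split.

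Of 17 measured genes of the ILC2 list, 6 fell in deficient lesions and none rose over all genes, and 10 fell and 1 rose adjusted over the list alone (median −0.96). Gata3, the transcription factor of ILC2s, fell by 1.53 ± 0.34 (adjusted p = 0.00412), Il1rl1, the IL-33 receptor gene, by 1.72 ± 0.38 (adjusted p = 0.00382) and the receptor gene Il9r by 1.74 ± 0.31 (adjusted p = 0.000632). The list was lower by limma's camera test at an inter-gene correlation of 0.01 (adjusted p = 3.46e-05, but adjusted p = 0.099 with an estimated correlation). Of 20 measured type 2 response genes, 9 fell and 1 rose, and adjusted over the list alone 13 fell and 1 rose (median −1.35, camera adjusted p = 1.08e-08, adjusted p = 0.107 with an estimated correlation). Ccl24, the eosinophil chemokine eotaxin-2, fell by 2.16 ± 0.44 (adjusted p = 0.00175). Of 6 measured eosinophil genes Ear2 fell over all genes and 3 adjusted over the list alone (median −0.80, camera adjusted p = 0.00169, adjusted p = 0.107 with an estimated correlation). The remaining genes of the fixed panel did not pass. Nmur1 was at −2.20 ± 0.81 (adjusted p = 0.0755), Prg2 at −1.82 ± 0.63 (0.0579) and Arg1 at −1.35 ± 0.58 (0.132). Klrg1 was at −0.96 ± 0.37 (0.0905), Siglecf at −0.83 ± 0.30 (0.0675), Ccl11 at −0.72 ± 0.29 (0.104), Mrc1 at −0.49 ± 0.28 (0.275) and Il33 at 0.37 ± 0.34 (0.544). Areg and Epx were not analysed here.

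**Figure D2:**
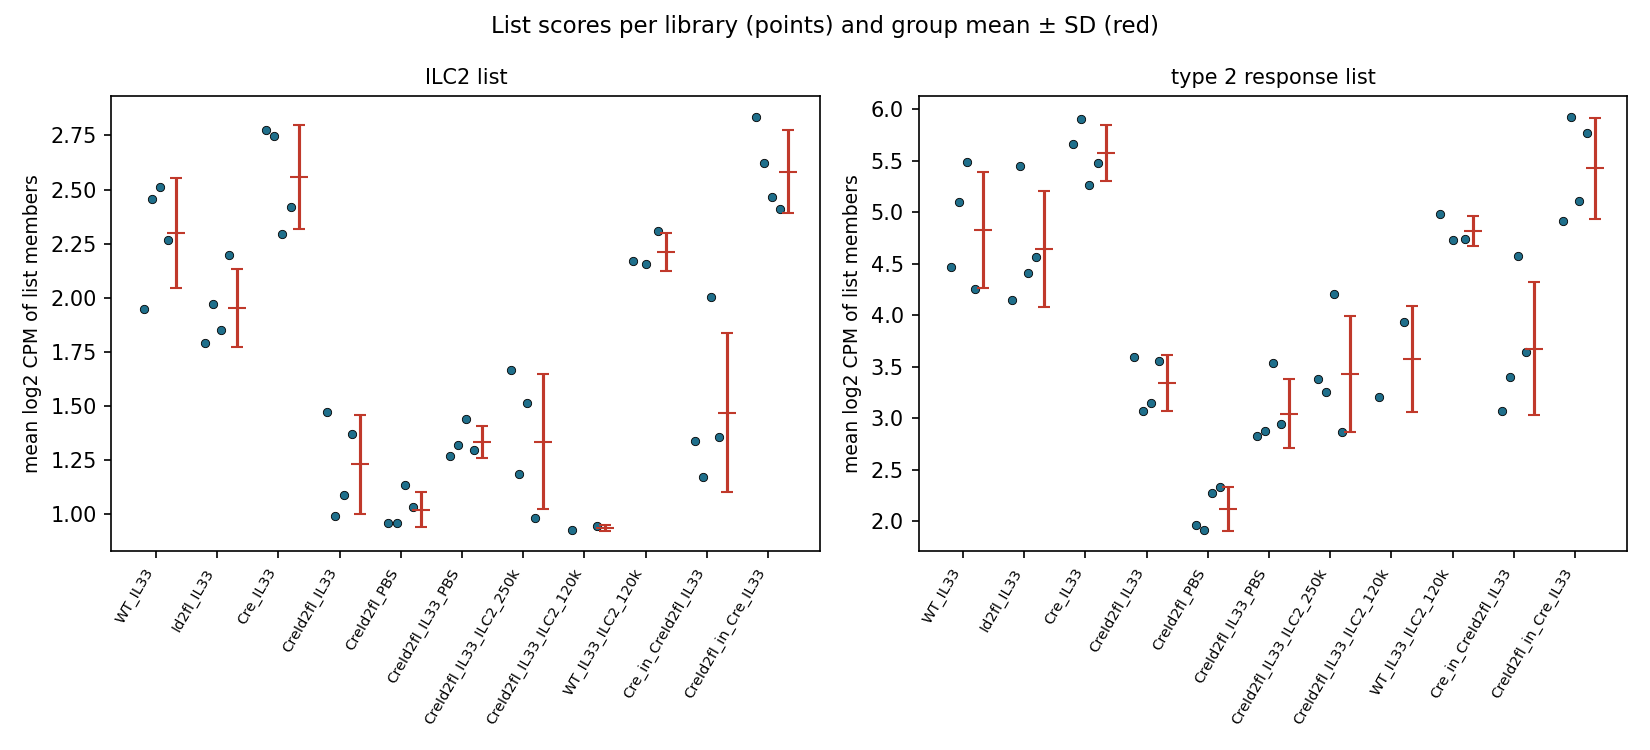
Mean log2 CPM of the measured ILC2 list genes (left) and type 2 response list genes (right) in each library (points), with the group mean ± SD in red; group names are as in the plot of tissue shares. The ILC2 score was 1.23 ± 0.23 in deficient lesions and 2.56 ± 0.24 in Cre controls, and the type 2 score 3.34 ± 0.27 and 5.58 ± 0.27 (n = 4 each).

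Cell-division genes were higher in the IL-33-treated deficient group of this comparison. All 15 genes of the proliferation list rose, over all genes and adjusted over the list alone (median 1.28). The mitotic kinase gene Bub1 rose (1.84 ± 0.27, adjusted p = 7.72e-05), cyclin B1 (Ccnb1, 1.64 ± 0.27, adjusted p = 0.000308) and Cdk1 (1.46 ± 0.24, adjusted p = 0.000243). The list's camera adjusted p was 8.91e-18 (0.107 with an estimated correlation). Of 15 interferon-response genes 5 rose, and 8 adjusted over the list alone (median 1.02, camera adjusted p = 0.000335, adjusted p = 0.808 with an estimated correlation). Irf7 was at 1.44 ± 0.40 (adjusted p = 0.0178), Isg15 at 1.38 ± 0.36 (0.0121) and Oas1a at 1.02 ± 0.26 (0.00932). Of 11 estrogen-response genes 4 rose, and 5 adjusted over the list alone (median 0.94, camera adjusted p = 0.000691, adjusted p = 0.342 with an estimated correlation). They included the estrogen-induced gene Greb1 (2.07 ± 0.47, adjusted p = 0.00412), the growth factor Igf1 (0.90 ± 0.24, 0.0121) and cyclin D1 (Ccnd1, 0.94 ± 0.26, 0.0171). Of 16 endometrial epithelium genes only the keratin Krt19 rose (2.05 ± 0.68, adjusted p = 0.046), and none adjusted over the list alone (median 1.15, camera adjusted p = 0.00169, adjusted p = 0.858 with an estimated correlation). Of 11 mast cell and basophil genes the mast cell protease gene Cpa3 rose (1.09 ± 0.36, adjusted p = 0.0469), and none adjusted over the list alone (median 0.48, camera adjusted p = 0.0312, adjusted p = 0.808 with an estimated correlation).

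The largest rises in deficient lesions were those of Guca2b, which encodes the gut peptide uroguanylin (5.96 ± 1.23, adjusted p = 0.0021), the adipocyte hormone leptin (Lep, 5.65 ± 1.04, 0.0008) and the epithelial small proline-rich gene Sprr2d (4.87 ± 1.26, 0.0117). Next were the water channel Aqp8 (4.03 ± 1.15, 0.0207), Tmprss11g (3.81 ± 1.15, 0.0285) and Clca3b (3.68 ± 1.04, 0.0198). In each of these only 1 or 2 of the 4 deficient libraries lay above all 12 competent ones. Mrgprg (−3.91 ± 1.06, adjusted p = 0.0162) and Mir6236 (−3.85 ± 1.26, 0.0436) were the other 2 of the 6 largest falls beside Chil3, Rnase2a, Ccl17 and Retnla. Among lists that camera did not call, adipocyte genes had a median of 1.93 with 3 of 10 members higher (camera adjusted p = 0.981). Type 17 and acute inflammation genes had a median of 0.56 with 3 of 11 higher (0.261; not called in any comparison here). Neutrophil genes had a median of 0.21 (0.343), resident peritoneal macrophage genes −0.06 (0.454), dendritic cell genes −0.20 (0.454) and B cell and plasma cell genes −0.33 (0.511). For NK and cytotoxic genes it was 0.30 (0.587), for endothelium genes 0.00 (0.580) and for smooth muscle genes 0.17 (0.454). Endometrial stroma (0.05, 0.642), blood (0.09, 0.642) and nerve genes (0.01, 0.621) were not called either.

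By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2329 of 21249 genes differed between deficient and competent lesions, 1325 higher and 1004 lower, of which 500 and 209 by at least 2-fold. Liver transcripts were high in 3 of the 16 libraries compared (1 wild-type, 1 Cre-control and 1 deficient), and without the liver libraries 1823 genes passed. Without replicate 4 of the deficient group the count was 698, and without its replicate 2, the deficient library with liver transcripts, 1433. Against the Cre controls alone, whose library names interleave with the deficient ones, 813 genes passed.

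As labelled, lesion transfer separated the genotype of the recipient from that of the fragment. Across both fragment genotypes (8 libraries from deficient recipients against 8 from Cre-control recipients), Il13 was 21.6-fold lower in deficient recipients (−4.44 ± 0.41, adjusted p = 1.88e-08) and Il5 14-fold (−3.81 ± 0.38, 8.81e-08). So were Chil3 37.9-fold (−5.25 ± 0.76, 3.15e-05) and Ear2 8.06-fold (−3.01 ± 0.28, 1.41e-08). Il1rl1 (chromosome 1, 40429570 to 40465415) was 5.93-fold lower (−2.57 ± 0.31, adjusted p = 2.58e-06). Col6a5 (chromosome 9, 105856078 to 105960643), a collagen VI chain, was 12.9-fold lower (−3.69 ± 0.38, adjusted p = 1.52e-07). It stood at 1927 ± 221 CPM for Cre fragments and 2330 ± 318 for deficient fragments in Cre recipients, against 159 ± 50.4 and 170 ± 91.3 in deficient recipients (SD, n = 4 each). Chil3 stood at 2868 ± 2193 CPM in deficient fragments in Cre recipients and at 131 ± 136 in Cre fragments in deficient recipients (n = 4 each). Of the 16 measured panel genes, 8 (Il5, Il13, Chil3, Retnla, Il1rl1, Nmur1, Ccl11 and Ccl24) had all 8 libraries from deficient recipients below all 8 from Cre recipients, which chance gives a gene in 0.0155% of cases in either direction.

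**Figure D3:**
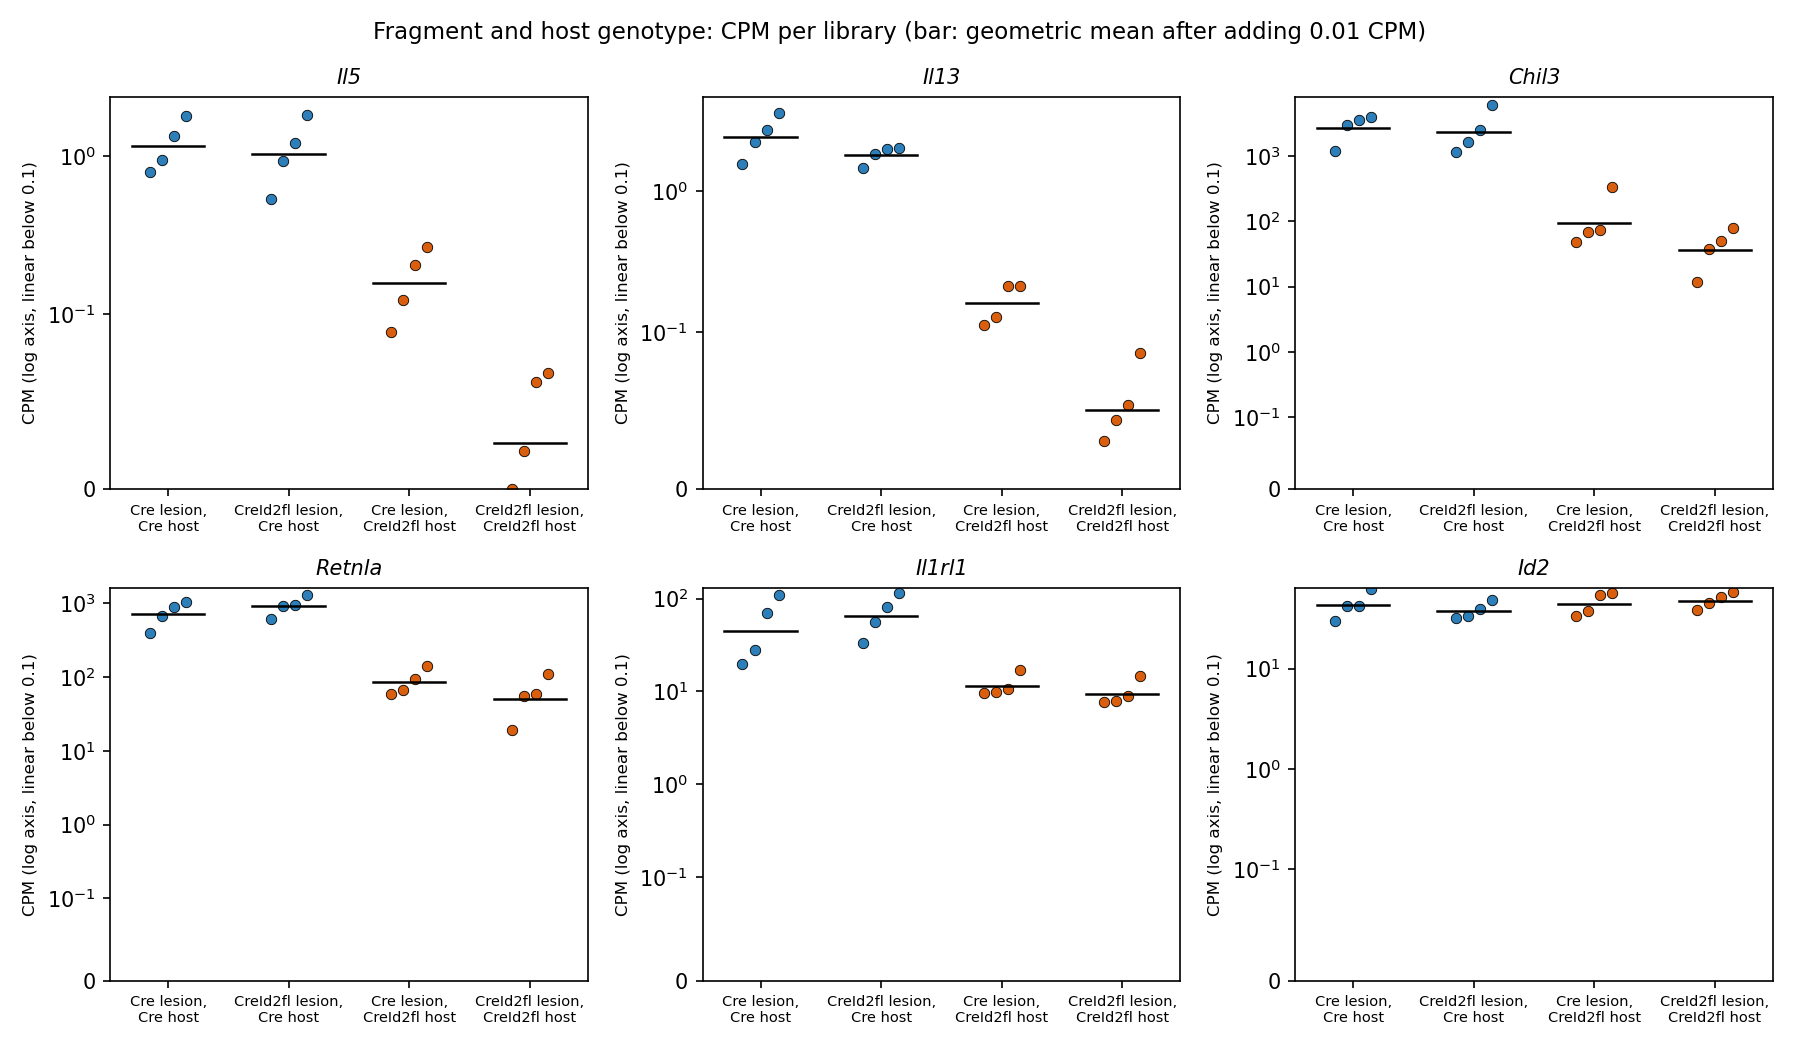
CPM of Il5, Il13, Chil3, Retnla, Il1rl1 and Id2 in each library (points) of the 4 combinations of fragment and recipient genotype, on a log axis that is linear below 0.1, with blue for Cre-control and orange for deficient recipients and bars at the geometric mean after adding 0.01 CPM. Apart from Id2, the values follow the recipient: Il13 averaged 2.51 ± 0.845 and 1.80 ± 0.251 CPM in Cre recipients and 0.166 ± 0.0536 and 0.0538 ± 0.0239 in deficient ones (n = 4 each).

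Of the 20 type 2 response genes 14 fell in deficient recipients and none rose, and adjusted over the list alone 16 fell (median −1.68). The camera adjusted p was 1.42e-17, and the call held with adjusted p = 0.00531 with an estimated correlation. Besides those named, Chil4 fell by 4.98 ± 1.21 (adjusted p = 0.00692), Ccl17 by 3.57 ± 0.44 (3.38e-06), Retnla by 3.52 ± 0.59 (0.000236), and Ccl24 by 2.52 ± 0.35 (1.66e-05). The arginase gene Arg1 fell by 1.98 ± 0.48 (0.00654), the eotaxin Ccl11 by 1.39 ± 0.24 (0.00039) and the mannose receptor Mrc1 by 1.14 ± 0.24 (0.00182). Of the 17 ILC2 genes 9 fell and none rose, and adjusted over the list alone 11 fell and 1 rose (median −0.93, camera adjusted p = 1.1e-09, held with adjusted p = 0.00333 with an estimated correlation). Nmur1, the receptor whose gene drives the Cre (chromosome 1, 86386303 to 86426228), fell by 3.38 ± 0.68 (adjusted p = 0.00153) and Gata3 by 1.15 ± 0.27 (0.00591). Of 6 eosinophil genes 2 fell (4 adjusted over the list alone), with a median of −0.84 (camera adjusted p = 0.00251, adjusted p = 0.159 with an estimated correlation). Siglecf fell by 0.86 ± 0.25 (adjusted p = 0.0208), while Prg2 was at −1.29 ± 0.49 (0.085).

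Among the other lists, 14 of 15 proliferation genes rose in deficient recipients (14 adjusted over the list alone). Their median was 1.13 (camera adjusted p = 6.58e-15, adjusted p = 0.159 with an estimated correlation). Bub1 was at 1.43 ± 0.26 (adjusted p = 0.000472), Ccnb1 at 1.40 ± 0.26 (0.000655) and Ccna2 at 1.31 ± 0.25 (0.000726). Interferon-response genes rose in 8 of 15 (11 adjusted over the list alone). Their median was 1.09 (camera adjusted p = 3.36e-07, adjusted p = 0.48 with an estimated correlation). Ifit1 was at 1.74 ± 0.38 (adjusted p = 0.00321), Irf7 at 1.66 ± 0.38 (0.0041) and Isg15 at 1.5 ± 0.34 (0.00378). Of 16 macrophage and monocyte genes 4 fell and 1 rose (9 and 1 adjusted over the list alone). Their median was −0.47 (camera adjusted p = 0.00692, adjusted p = 0.701 with an estimated correlation). Folr2, a tissue-resident macrophage marker, was at −1.0 ± 0.25 (adjusted p = 0.00885), the phagocytic receptor Mertk at −0.53 ± 0.16 (0.0254) and Fcgr1 at 0.91 ± 0.26 (0.02). Of 10 regulatory T cell genes Il2ra, which also stands in the ILC2 list, fell by 1.86 ± 0.31 (adjusted p = 0.000177) and Lrrc32 by 0.41 ± 0.14 (0.0436), while Ikzf2 rose by 0.79 ± 0.25 (0.0397). In this list 3 fell and 1 rose adjusted over the list alone (median −0.31, camera adjusted p = 0.0317, adjusted p = 0.701 with an estimated correlation).

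Of 11 immediate early and stress genes 3 fell in deficient recipients (5 adjusted over the list alone). Their median was −0.40 (camera adjusted p = 0.0328, adjusted p = 0.674 with an estimated correlation). Atf3 was at −1.0 ± 0.23 (adjusted p = 0.00422), Jun at −0.65 ± 0.13 (0.00131) and Ier2 at −0.50 ± 0.14 (0.019). Of 9 mesothelium genes Lrrn4 fell (−1.43 ± 0.46, adjusted p = 0.0413; 1 adjusted over the list alone). Their median was −0.71 (camera adjusted p = 0.0165, adjusted p = 0.701 with an estimated correlation). Of 9 mitochondrial transcripts 2 rose (5 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.000549, adjusted p = 0.673 with an estimated correlation). The 2 were mt-Nd1 (0.73 ± 0.23, adjusted p = 0.0357) and mt-Nd2 (0.98 ± 0.29, 0.0271). Of 11 estrogen-response genes Greb1 rose (1.70 ± 0.45, adjusted p = 0.0132; 1 adjusted over the list alone). Their median was 0.95 (camera adjusted p = 0.0317, adjusted p = 0.701 with an estimated correlation). No skeletal muscle gene passed (median 0.69, camera adjusted p = 0.0216, adjusted p = 0.858 with an estimated correlation).

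Of 14 T cell genes Cd4 (1.42 ± 0.41, adjusted p = 0.0222), Cd8a (2.31 ± 0.68, 0.0238) and Cd8b1 (2.34 ± 0.70, 0.0261) rose in deficient recipients, and 4 adjusted over the list alone (median 1.03, camera adjusted p = 0.00745, adjusted p = 0.828 with an estimated correlation). These rises rested on replicate 3 of the Cre fragments in deficient recipients. Without it Cd8a was at 0.48 (adjusted p = 0.552), Cd8b1 at 0.38 (0.655) and Cd4 at 0.97 (0.0912). In deficient fragments alone the difference ran the other way, at −1.79 for Cd8a, −1.15 for Cd8b1 and −0.15 for Cd4. The largest rises in deficient recipients were Lep (6.28 ± 1.22, adjusted p = 0.00101), Sprr2d (5.13 ± 1.40, 0.0155) and the immunoglobulin gene Ighg2c (3.75 ± 1.14, 0.0298). Next came the fatty acid desaturase Scd1 (3.31 ± 0.74, 0.00359), the adipokine gene Retn (3.29 ± 0.77, 0.00515) and the sodium-glucose transporter Slc5a1 (3.10 ± 1.03, 0.0461). Beside Chil3, Chil4 and Col6a5, the largest falls were Rnase2a (−4.61 ± 0.58, adjusted p = 4.58e-06), Igkv12-89 (−4.61 ± 1.25, 0.0146), an immunoglobulin segment whose reads relatives can share, and Gsdmc2 (−3.61 ± 1.21, 0.0487).

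In all, 2403 genes differed by recipient genotype (1066 higher and 1337 lower in deficient recipients; 387 and 272 by at least 2-fold), and 1 gene by fragment genotype. Each lesion-transfer group has its own run of library names, while those of lesions not transferred interleave. There 813 genes differed and 11 of 20 type 2 genes fell. Of 23 chromosome 12 genes differing between Cre and floxed controls, 22 passed there and none by fragment genotype. So 1 gene does not show a small effect of the fragment.

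The transferred lesions taken alone (Cre fragments in deficient recipients against deficient fragments in Cre recipients, n = 4 each) were examined as the target of gene sets from the first comparison, with which they share no library. Of the 100 genes with the smallest p among those higher in deficient than in competent lesions, 98 had the same sign here and 26 passed (median 1.03, camera p = 2.13e-46, p = 0.00235 with an estimated correlation). Of the 100 lower genes 95 had the same sign and 30 passed (median −0.48, camera p = 3.61e-49, p = 5.22e-05 with an estimated correlation). In these lesions 214 genes differed, 89 higher and 125 lower in deficient recipients. Among the largest falls were Rnase2a (−4.50 ± 0.82, adjusted p = 0.00444), Chil3 (−4.45 ± 1.03, 0.0244), and Col6a5 (−3.87 ± 0.54, 0.000254). The carbonic anhydrase Car4 (−3.42 ± 0.88, 0.0473) and Retnla (−3.39 ± 0.83, 0.0366) fell too. The largest rises were Lep (7.38 ± 1.90, adjusted p = 0.0488), resting on 585 counts against 3 (ratio 202, 95% counting interval 68.7 to 981). Next were the imprinted gene Peg10 (3.43 ± 0.66, 0.00692), Ms4a4c (3.09 ± 0.60, 0.00788), the Wnt antagonist Sfrp4 (2.88 ± 0.44, 0.000609), the interferon-inducible Ifi213 (2.53 ± 0.64, 0.0419) and the potassium channel Kcnk2 (2.50 ± 0.54, 0.0163).

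In the transferred lesions 8 of 20 type 2 genes fell (15 adjusted over the list alone), with a median of −1.63 (camera adjusted p = 1.84e-17, held with adjusted p = 0.0055 with an estimated correlation). Of 17 ILC2 genes 4 fell (8 adjusted over the list alone), with a median of −0.65 (camera adjusted p = 6.59e-09, held with adjusted p = 0.0055 with an estimated correlation). Il13 fell by 3.43 ± 0.55 (adjusted p = 0.00128), Il5 by 2.70 ± 0.49 (0.00444), Il1rl1 by 2.60 ± 0.44 (0.00241), and Nmur1 by 4.42 ± 1.03 (0.0246). Ccl24 fell by 2.20 ± 0.48 (0.0173), Ccl11 by 1.57 ± 0.35 (0.0178) and Mrc1 by 1.34 ± 0.34 (0.0407). Interferon-response genes rose in 4 of 15 (8 adjusted over the list alone). Their median was 1.59 (camera adjusted p = 3.1e-11, adjusted p = 0.257 with an estimated correlation). Ifit1 was at 2.43 ± 0.56 (adjusted p = 0.0232). The proliferation marker Mki67 rose by 1.22 ± 0.31 (adjusted p = 0.0415) and the matrix protein Thbs2 by 1.35 ± 0.34 (0.0415). Blood (median 2.30, camera adjusted p = 0.00159), adipocyte (1.74, 0.022), T cell (1.62, 0.000389), proliferation (1.10, 1.91e-12), B cell (0.78, 0.0194), mitochondrial (0.78, 1.83e-06) and neutrophil genes (0.65, 0.0194) were called higher. Called lower were mesothelium (−1.10, 0.000206), eosinophil (−0.65, 0.022), macrophage (−0.43, 0.018) and extracellular matrix genes (−0.23, 0.0324). These 11 lists had adjusted p from 0.257 to 0.633 with an estimated correlation. Without replicate 2 of the deficient fragments in Cre recipients 54 genes passed and without its replicate 4 the count was 66. A fit to these 8 libraries alone gave 3, and without the liver libraries, none of which is among the 8, the count was 355.

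For the genotype of the fragment, the gene that passed was Gm7993, a processed pseudogene (chromosome 5, 95974240 to 95975623; 2.13, adjusted p = 0.0101), named after its values were seen because it lies outside the naming rule. Bicd1 (0.67 ± 0.16, adjusted p = 0.331) and the monocyte gene Ly6c2 (−1.98 ± 0.59, 1.00) did not pass. At an unadjusted p of 0.05, 834 genes passed against 1062 by chance. Mast cell genes were higher with deficient fragments (median 0.62, camera adjusted p = 4.26e-05, adjusted p = 0.515 with an estimated correlation; 1 of 11 higher adjusted over the list alone). Blood genes were lower (median −1.32, camera adjusted p = 2.07e-05, adjusted p = 0.515 with an estimated correlation; 6 of 6 lower adjusted over the list alone). B cell (median −0.68, camera adjusted p = 0.000169), interferon-response (−0.44, 0.00252), neutrophil (−0.41, 0.00921), regulatory T cell (−0.36, 0.0252) and mitochondrial genes (−0.16, 0.0189) were called lower. Mesothelium (0.38, 0.0189), nerve (0.32, 0.0194) and extracellular matrix genes (0.15, 0.0252) were called higher. These 8 lists had adjusted p from 0.665 to 0.715 with an estimated correlation. No gene passed without replicate 1 or 2 of the Cre controls, without replicate 4 of the deficient fragments in Cre recipients or without the liver libraries. The count was 2 without replicate 3 of the deficient group and 3 without replicate 1 of the deficient fragments in Cre recipients. Leaving out replicate 1 of the Cre fragments in deficient recipients gave 7, DESeq2 13 and limma with quality weights 2, both lower.

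Within ILC2-deficient mice, IL-33 was compared with PBS (n = 4 each, in separate runs of library names). Col6a5 rose from 14.9 ± 4.20 to 170 ± 91.3 CPM (3.51 ± 0.53, adjusted p = 0.00448), and Rnase2a (chromosome 14, 51255262 to 51256112) rose by 7.35 ± 1.16 (adjusted p = 0.00452), from 3 counts over the PBS group to 395 (ratio 192, 95% counting interval 65.2 to 935). Retnla stood at 59.9 ± 36.5 CPM against 5.89 ± 5.29 and did not pass (3.34 ± 0.83, adjusted p = 0.528). Of the 20 type 2 genes none passed over all genes and 5 rose adjusted over the list alone (median 0.73, camera adjusted p = 6.04e-06, adjusted p = 0.433 with an estimated correlation). Il13 rested on 9 counts against 2 (ratio 6.56, 95% counting interval 1.36 to 62.4).

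Proliferation genes had a median of 0.85 under IL-33 with none passing over all genes and 10 of 15 higher adjusted over the list alone (camera adjusted p = 6.8e-14, adjusted p = 0.433 with an estimated correlation). Plk1 was at 1.10 ± 0.35 (adjusted p = 0.62). The endometrial epithelium list (median 1.49, camera adjusted p = 7.75e-05, adjusted p = 0.994 with an estimated correlation; Krt19 2.18 ± 0.94, 0.654) and the mast cell list (median 1.06, camera adjusted p = 0.00102, adjusted p = 0.632 with an estimated correlation) were also higher, with no member passing either way. Adipocyte genes had a median of 2.11, all 10 above 0, with none passing either way and the list not called (camera adjusted p = 0.127). Their score was 3.17 ± 2.34 under IL-33, from 0.782 to 6.39, against 2.70 ± 0.81. With the group with added PBS in place of the IL-33 group, the epithelium list was called lower than under PBS alone (median −2.24, camera adjusted p = 5.81e-06) and the type 2 list higher (1.14, 2.87e-07), while the proliferation and mast cell lists were not called (0.657 each). In the IL-33 group ILC2 genes were not called (median 0.21, camera adjusted p = 0.61), nor were eosinophil genes, whose median (−0.07) and mean (0.42) differ in sign. The clock genes Arntl (−0.60 ± 0.15) and Npas2 (−0.73 ± 0.19) were at an adjusted p of 0.528. Col6a5 and Rnase2a were the only 2 genes called of 21249, with 1436 at an unadjusted p of 0.05. No gene passed without the liver libraries (Col6a5 3.11, adjusted p = 0.0703; Rnase2a 6.89, 0.0739), without PBS replicate 2 (both 0.0536) or without PBS replicate 4. Without PBS replicate 1 only Col6a5 passed, without replicate 3 of the IL-33 group 4 genes passed, and a fit to these 8 libraries alone gave 0 (both 0.398). DESeq2 called 18 genes and limma with quality weights 24, where Rnase2a missed the threshold (7.30, adjusted p = 0.231).

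Transfer of ILC2s into deficient mice was tested with 250000 cells against IL-33 with added PBS (n = 4 each). Type 2 levels were spread widely after transfer: Chil3 was 357 ± 558 CPM against 89.6 ± 40 and Retnla 193 ± 296 against 164 ± 73.8 (SD, n = 4 each), with replicate 3 at 1191 and 636 CPM. The ILC2 score was 1.34 ± 0.31 after transfer and 1.33 ± 0.07 without, and the type 2 score 3.43 ± 0.57 and 3.05 ± 0.33. Il5 (0.64 ± 0.57, adjusted p = 0.725), Il13 (0.43 ± 0.57, 0.833) and Chil3 (1.99 ± 0.93, 0.571), named for this comparison after their values were seen, did not pass. The ILC2 list (median 0.01, camera adjusted p = 0.394) and the type 2 list (median 0.29, mean 0.70, camera direction lower, adjusted p = 0.789) were not called.

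Camera called 12 lists in this comparison, and none held with an estimated correlation. Mitochondrial transcripts were lower after 250000 ILC2s, with none of 9 passing over all genes and 8 lower adjusted over the list alone (median −1.0, camera adjusted p = 5.07e-10, adjusted p = 0.411 with an estimated correlation; mt-Nd2 −1.39 ± 0.42, 0.567). Skeletal muscle (median −1.11, camera adjusted p = 2.68e-08), blood (−1.55, 0.000368), B cell (−0.64, 0.0033), adipocyte (−0.63, 0.00984), dendritic cell (−0.40, 0.0398) and macrophage genes (−0.18, 0.0284) were lower too. Proliferation (0.50, 7.79e-05), endometrial epithelium (2.11, 0.0033), smooth muscle (1.59, 0.00747), endometrial stroma (0.63, 0.0339) and mast cell genes (0.38, 0.0478) were higher. With the IL-33 group as the control in place of added PBS, the epithelium (median −1.49, camera adjusted p = 7.74e-09) and proliferation lists (−0.24, 0.0035) were called lower after 250000 ILC2s. Adipocyte genes were lower against either control (−1.93, 0.0272), as were skeletal muscle genes by camera's direction (median 0.14, 0.000976), and the other 8 lists were not called. The last 11 lists of the main comparison had adjusted p from 0.68 to 0.722 with an estimated correlation, and no member of them passed, over all genes or adjusted over the list alone. The muscle share was 0.0123% in replicate 4 of the transferred group.

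No gene passed edgeR's test after 250000 ILC2s, with 1849 at an unadjusted p of 0.05; the smallest adjusted p was 0.348. DESeq2 called 14 genes and limma 1107 (245 higher and 862 lower). The cold-inducible gene Cirbp was at 0.61 ± 0.15 and the clock gene Arntl at −0.69 ± 0.15 (adjusted p = 0.567 each). Of the same 100 higher genes from deficient against competent lesions 80 were also higher after transfer (median 0.25, camera p = 0.000256, p = 0.403 with an estimated correlation). Of the 100 lower ones 21 were lower (median 0.17, camera p = 1.53e-05 towards higher, p = 0.177 with an estimated correlation), and no member passed. The sets were not tested against the IL-33 group, against which the epithelium and proliferation lists were lower. Of the 100 genes with the smallest p among those higher under IL-33 in deficient mice 70 were higher after transfer (camera p = 0.0122, p = 0.305 with an estimated correlation), and of the 100 so taken among those lower 47 were lower (camera p = 0.276).

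Transfer of 120000 ILC2s into deficient mice (n = 2 against 4, in separate runs of library names) gave a type 2 score of 3.57 ± 0.51 against 3.34 ± 0.27 and an ILC2 score of 0.94 ± 0.01 against 1.23 ± 0.23. The neutrophil list was higher, with none of 12 genes passing over all genes and 5 higher adjusted over the list alone (median 1.16, camera adjusted p = 5.09e-12, adjusted p = 0.0965 with an estimated correlation). Its members included the granule genes Ngp (3.96 ± 1.31) and S100a9 (1.91 ± 0.73), each at an adjusted p of 1.00. Eosinophil (median 0.69, camera adjusted p = 0.00379, adjusted p = 0.194 with an estimated correlation; Ear2 1.13 ± 0.43) and interferon-response genes (0.49, 4.44e-06, 0.539) were called higher. So were adipocyte (0.16, 4.43e-11, 0.188) and macrophage genes (0.21, 0.0368, 0.902). Mast cell (−1.21, 8.87e-05, adjusted p = 0.276 with an estimated correlation), proliferation (−0.22, 0.00547, 0.902) and nerve genes (−0.52, 0.0354, 0.851) were called lower. With the group with added PBS as the control the proliferation list was called higher (median 0.53, camera adjusted p = 0.00053), and the eosinophil, macrophage, mast cell and nerve lists were not called. The neutrophil (1.56, 4.04e-06), interferon-response (0.95, 0.000116) and adipocyte lists (1.60, 0.000176) were again higher. Skeletal muscle genes had a median of 0.17 and a mean of 0.20 while camera's direction was lower (adjusted p = 4.02e-11, adjusted p = 0.379 with an estimated correlation). The muscle shares of both libraries were 0.0117% and 12.1%. No gene passed edgeR's test, with 400 at an unadjusted p of 0.05 against 1062 by chance. DESeq2 called 9 and limma with quality weights 0. The neutrophil gene Cd177 (2.87 ± 0.85) and the clock genes Dbp (−1.27 ± 0.35) and Per3 (−0.92 ± 0.24) had an adjusted p of 1.00. Without replicate 2 of the transferred group 1 gene passed.

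The same transfer into wild-type mice (n = 3 against 4) left the type 2 score at 4.82 ± 0.14 against 4.83 ± 0.57 and the ILC2 score at 2.21 ± 0.09 against 2.30 ± 0.25. Extracellular matrix genes (median −0.22, camera adjusted p = 0.00253), macrophage genes (−0.28, 0.0112) and mast cell genes (−0.39, 0.0289) were called lower. Endometrial epithelium genes were called higher (1.36, 0.0203). Each list had adjusted p = 0.966 with an estimated correlation, and no member passed either way. Replicate 3 of the transferred group and replicate 4 of the other held liver transcripts. No gene passed edgeR's test, with 841 at an unadjusted p of 0.05 against 1062 by chance. DESeq2 called 3 and limma with quality weights 0. The elastase gene Cela1 was at 2.69 ± 0.59 and Sesn1 at −0.77 ± 0.17 (adjusted p = 0.456 each). Leaving out replicate 1 or replicate 2 of the transferred group gave 2 genes each, and muscle, epithelium and liver scores as covariates 1.

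**Figure D4:**
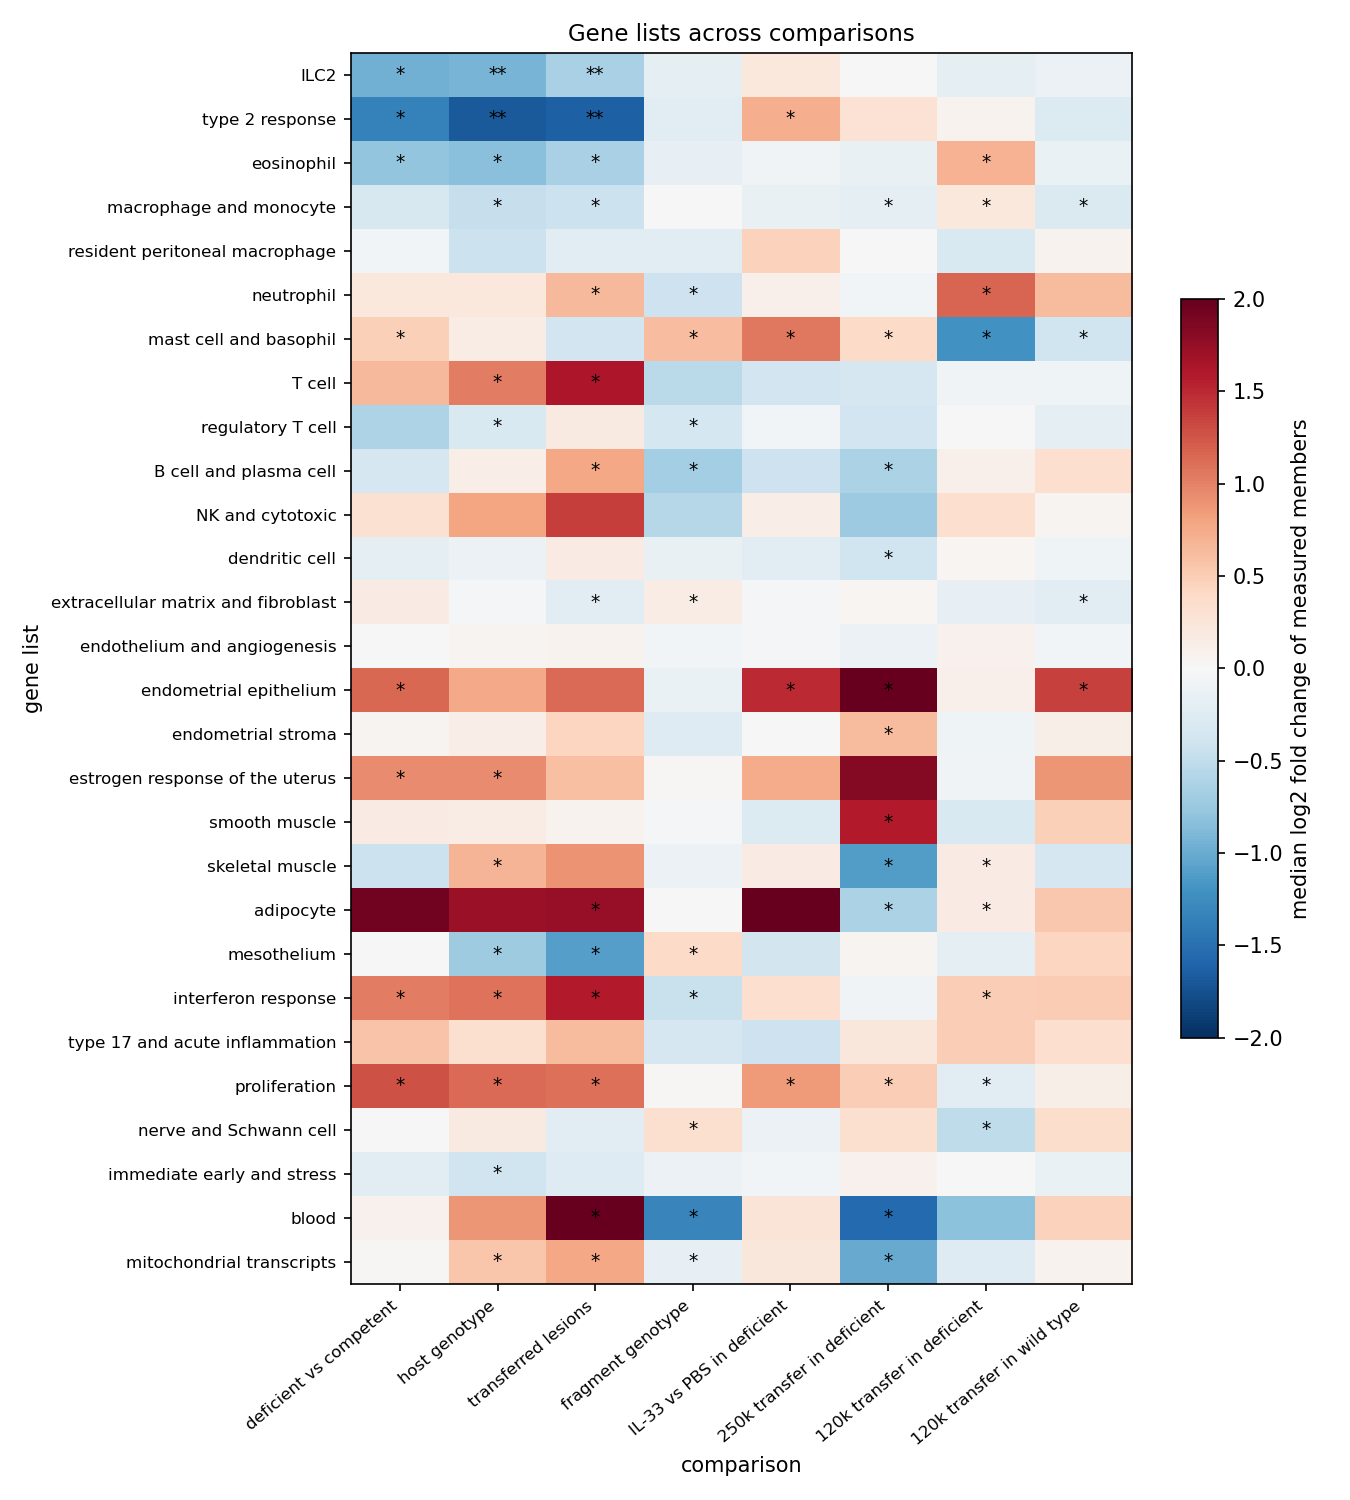
Median log2 fold change of the measured members of 28 gene lists (vertical axis) in 8 comparisons (horizontal axis), from blue (lower) to red (higher) on a scale that ends at −2 and 2; * marks a camera adjusted p below 0.05 at a correlation of 0.01, and ** that it held with an estimated correlation. Only the ILC2 and type 2 response lists carry **, by recipient genotype (medians −0.93 and −1.68) and in the transferred lesions (−0.65 and −1.63).

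The difference between transfers was tested as an interaction. For 120000 ILC2s in deficient against wild-type recipients, the eosinophil list (median 0.57, camera adjusted p = 0.00399, adjusted p = 0.489 with an estimated correlation; Ear2 1.63 ± 0.59) was called higher. So were macrophage (0.48, 0.00115, adjusted p = 0.978 with an estimated correlation) and neutrophil genes (1.14, 0.0134, 0.978), while proliferation genes were called lower (−0.36, 0.0453, 0.978). For adipocyte genes the median (−0.41) and camera's direction (higher, 0.00115) differed in sign, as they did for skeletal muscle genes (0.51 and lower, 0.00268). No gene passed, with 686 at an unadjusted p of 0.05, 8 by DESeq2 and 0 by limma with quality weights. For 250000 against 120000 ILC2s in deficient recipients, each against its own control group, 17 lists were called. The smallest p-values were those of adipocyte (median −0.88, camera adjusted p = 3.55e-10), proliferation (0.75, 2.19e-07), neutrophil (−1.02, 3.46e-06) and mast cell genes (1.39, 1.77e-05). The control groups themselves differed, with a proliferation median of −0.79 for added PBS against IL-33. With 1 control for both transfers, which leaves 250000 against 120000 cells, adipocyte (−2.14, 4.8e-15), neutrophil (−1.24, 7.05e-12), mast cell (0.99, 0.00305) and interferon-response genes (−1.02, 3.08e-11) were called the same way. Epithelium (−1.58, 7.05e-12) and estrogen-response genes (−0.33, 0.00157) were called the other way, and the other 11 lists, proliferation among them (−0.07, 0.751), were not called. These 6 calls had adjusted p from 0.0588 to 0.463 with an estimated correlation. In the main test of the 17 lists the adjusted p was from 0.254 to 0.6 with an estimated correlation. In a fit to these groups with the replicate number as a block, which paired the IL-33 group with that given 250000 ILC2s, the endometrial stroma (camera adjusted p = 0.0798) and blood lists (0.0583) were not called and the other 15 were. No gene passed here either, with 858 at an unadjusted p of 0.05, 29 by DESeq2 and 0 by limma with quality weights. A fit to the compared groups alone gave 2. The clock genes Dbp (2.30 ± 0.45, adjusted p = 0.336), Per3 (1.16 ± 0.30, 0.98) and Arntl (−1.12 ± 0.24, 0.552) did not pass.

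The competent genotypes were compared with each other to see how far they differ. Between Cre and floxed controls (n = 4 each, in separate runs of library names) 70 genes differed, 38 higher and 32 lower in Cre controls. Within the naming rule the largest rises were Zfp125 (2.58 ± 0.37, adjusted p = 0.000112; chromosome 12, 20877084 to 20921262, annotated as a transcribed pseudogene), Ch25h, an oxysterol enzyme (2.34 ± 0.45, 0.00553), and the interleukin-2 receptor gene Il2ra (2.01 ± 0.44, 0.0237). Next were the activin subunit Inhba (1.68 ± 0.27, 0.000605), Dubr (1.57 ± 0.24, 0.000254) and Qpct (1.54 ± 0.28, 0.00334). Lower were Adamts20 (−2.68 ± 0.63, adjusted p = 0.0489), Dynlt1b (−0.90 ± 0.21, 0.047), Vcpkmt (−0.72 ± 0.13, 0.00172) and Gpatch11 (−0.55 ± 0.09, 0.00142). Of the 66 called genes with a unique position 23 lay on chromosome 12, where Id2 lies. All 23 also passed by recipient genotype and none by fragment genotype. ILC2 genes were higher in Cre controls (1 of 17, and 5 adjusted over the list alone; median 0.52, camera adjusted p = 6.07e-05, adjusted p = 0.116 with an estimated correlation; Il1rl1 1.66 ± 0.43, 0.0989). So were type 2 genes (0 of 20, and 5 adjusted over the list alone; median 0.53, camera adjusted p = 4.8e-06, adjusted p = 0.414 with an estimated correlation; Ccl24 1.90 ± 0.48, 0.0845) and mesothelium genes (0 of 9, and 6 adjusted over the list alone; median 1.33, camera adjusted p = 8.99e-05, adjusted p = 0.567 with an estimated correlation). Resident peritoneal macrophage (median 0.77, camera adjusted p = 0.0135), neutrophil (0.75, 0.0026), regulatory T cell (0.64, 0.00304), macrophage (0.37, 0.0026) and immediate early genes (0.51, 0.0134) were called higher. Called lower were skeletal muscle (−1.67, 3.85e-06) and mitochondrial genes (−0.31, 0.00571). These 7 lists had adjusted p from 0.567 to 0.596 with an estimated correlation. Without replicate 1 of the Cre controls 45 genes passed, among genes with a mean CPM of at least 1 it was 37, and in a fit to both groups alone 36.

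Wild-type lesions were set against the mean of Cre and floxed controls (n = 4 against 8). The digestive enzyme genes Pnlip (7.27 ± 1.75, adjusted p = 0.0268) and Ctrb1 (5.71 ± 1.48, 0.0349) were higher in wild type. So were Trim63, a muscle ubiquitin ligase (3.14 ± 0.89, 0.0489), Ehhadh, a peroxisomal enzyme (3.07 ± 0.79, 0.0344), Depp1 (2.36 ± 0.52, 0.0144) and Dusp26 (1.86 ± 0.46, 0.0259). The chemokine Ccl7 (−1.76 ± 0.39, adjusted p = 0.0144), Isg15 (−1.58 ± 0.44, 0.0463), Oas2 (−1.40 ± 0.36, 0.0348), Sapcd2 (−1.38 ± 0.37, 0.04), Dbp (−1.37 ± 0.25, 0.00389) and Plekhh1 (−1.33 ± 0.34, 0.0309) were lower. Proliferation genes were lower (0 of 15, and 10 adjusted over the list alone; median −0.71, camera adjusted p = 9.22e-06; Aurkb −0.83 ± 0.26, 0.0741). So were endometrial epithelium (median −1.36, 0.00929; Krt19 −2.09 ± 0.87, 0.176) and interferon-response genes (−0.46, 0.0409; 1 of 15). Mesothelium (0.67, 0.0263) and mitochondrial genes (0.59, 0.0263) were higher. Each of the 5 lists had adjusted p = 0.962 with an estimated correlation. The type 2 list (median −0.36, camera adjusted p = 0.346) and the ILC2 list (−0.06, mean 0.05, 0.817) were not called. In all 563 genes differed, 368 higher and 195 lower, and 47 without the liver libraries, of which these 12 hold 2. Ehhadh was at −0.46 without replicate 4 of the wild type, a liver library. The count was 87 without that replicate, 121 without wild-type replicate 1 and 162 without replicate 2. It was 270 and 307 without replicates 4 and 2 of the floxed controls, 306 and 979 without replicates 2 and 3 of the Cre controls. The count was 31 in a fit to these groups alone.

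Deficient mice given IL-33 with added PBS differed from those given IL-33 (n = 4 each, in separate runs of library names) in 3 genes. The core clock gene Arntl (chromosome 7, 113207465 to 113314126) was higher, at 54 ± 7.19 against 28.0 ± 3.16 CPM (0.95 ± 0.16, adjusted p = 0.00902). The inositol synthase Isyna1 was lower (−1.09 ± 0.19, 0.0237), as was the fatty acid receptor Ffar4 (−1.53, 0.00902), which lies outside the naming rule and was named after its values were seen. Endometrial epithelium genes were lower, with none of 16 passing over all genes and 13 lower adjusted over the list alone (median −3.95, camera adjusted p = 4.08e-09; Krt19 −4.39 ± 1.04). So were proliferation genes (0 of 15, and 10 adjusted over the list alone; median −0.79, 7.73e-09) and estrogen-response genes (0 of 11, and 5 adjusted over the list alone; median −2.09, 6.73e-05; Greb1 −2.09 ± 0.65). Each of the 3 lists had adjusted p = 0.478 with an estimated correlation. Endothelium (median 0.34, camera adjusted p = 0.00114), B cell (1.30, 0.000128), mitochondrial (0.68, 0.000181) and dendritic cell genes (0.48, 0.00446) were higher with the same adjusted p = 0.478 with an estimated correlation. Smooth muscle (−1.41, 0.005), endometrial stroma (−0.72, 0.0311) and mast cell genes (−0.55, 0.0393) were called lower. The stroma list was called higher with muscle and epithelium scores as covariates (camera adjusted p = 0.0192). Called higher were macrophage (0.29, 0.0166), T cell (0.73, 0.0452) and skeletal muscle genes (1.28, 0.0452). These 6 lists had adjusted p from 0.685 to 0.72 with an estimated correlation. The type 2 list was not called (median 0.57, mean −0.23, camera adjusted p = 0.23). At an unadjusted p of 0.05, 3486 genes passed. No gene passed without replicate 1, 2 or 4 of the group with added PBS, with muscle and epithelium scores as covariates (Arntl 0.90, Isyna1 −0.70, both 0.323) or in a fit to both groups alone. Without replicates 4, 2 and 3 of the IL-33 group the counts were 1, 83 and 423, and without the liver libraries 163.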

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

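The tests with tissue scores, without the liver libraries and by run of library names, and the liver list, were chosen after the results were seen. In groups of 4 libraries, 117 sets of values were searched for a library far from the rest. In 14 sets one was found, where chance gives about 1 in 20 groups, or 5.85. The liver score was 11.8 in replicate 4 of the wild type (next highest −3.57), 11.4 in replicate 3 of the Cre controls (−2.57), 10.1 in replicate 2 of the IL-33-treated deficient group (−2.68) and 5.57 in replicate 2 of the group given 250000 ILC2s (−3.25). The T cell score was 5.36 in replicate 3 of the Cre fragments in deficient recipients (next highest 1.18) and 0.80 in replicate 3 of the floxed controls (0.04). In replicate 3 of the deficient group given PBS the skeletal muscle score was 7.19 (next lowest 9.98), Chil3 56.3 CPM (next highest 5.23) and Id2 83.1 CPM (48.9). In replicate 3 of the group given 250000 ILC2s Chil3 was at 1191 CPM (next highest 129) and Retnla at 636 (70.6). Chil3 was at 334 CPM in replicate 3 of the Cre fragments in deficient recipients (next highest 72.8). With added PBS the type 2 score was 3.54 in replicate 3 (next highest 2.95) and the proliferation score 3.35 in replicate 2 (next lowest 4.39). Tests of the difference between transfers called 6 lists by genotype and 17 by ILC2 number, and none held with an estimated correlation.

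Type 2 response genes were lower in deficient recipients of either fragment, with 14 of 20 passing (median −1.68). The tables argue against liver tissue as the cause, since 14 passed without the 4 liver libraries (median −1.75), and against muscle and epithelium content, since 15 passed with both scores as covariates (median −1.81). A difference between runs of libraries is argued against for the lesions not transferred, where 11 of 20 passed between groups whose library names interleave (median −1.83), but it stays open for the transferred lesions, each group of which has its own run. The missing ILC2s of the recipient are a candidate that the design names, while other effects of the recipient's genotype stay open, and no type 2 gene passed after either ILC2 transfer into deficient mice. All 23 chromosome 12 genes discussed below passed by recipient and none by fragment genotype, so the fragment labels stay unchecked.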

How the results depend on the processing

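Fits without the liver libraries, with epithelium or liver scores as covariates, among genes with a mean CPM of at least 1, to the transferred lesions alone, to the IL-33 group and the group given 250000 ILC2s alone, and with 1 control for both transfers were chosen after the results were seen. Of counts of genes or lists under alternatives other than leaving out a replicate, 101 stayed within 1.5 times and 60 did not. Of values of named genes 5435 kept direction and side of the threshold, 360 lost the call, 168 gained it and 3 changed sign, and of list tests 1019, 374, 0 and 14. Leaving out a replicate kept 5091 values of named genes, while 317 lost the call, 31 gained it and 1 changed sign. DESeq2's scaling in edgeR gave 2418 genes for deficient against competent lesions and 2373 for recipient genotype, with 62.0% and 50.5% higher against 56.9% and 44.4%. Without the liver libraries these counts were 1823 and 2295, and with DESeq2 3007 and 3023. For each value given next the cause was not tested. Depth limits genes with few counts, such as Il13 in deficient lesions.

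With the muscle score as a covariate IL-33 against PBS gave 4 genes, wild type against the other controls 1168 and the transferred lesions 379. With muscle and epithelium scores the counts were 4 for IL-33, 1293 for wild type and 0 for added PBS. With the liver score as well they were 1 for 120000 ILC2s in wild type, 1063 for wild type, 0 for added PBS and 419 for the transferred lesions. Without the liver libraries they were 0 for IL-33, 0 for fragment genotype, 47 for wild type, 163 for added PBS and 355 for the transferred lesions. Among genes with a mean CPM of at least 1, Cre against floxed controls gave 37.

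DESeq2 and limma with quality weights, in that order, gave 18 and 24 genes for IL-33, 14 and 1107 for 250000 ILC2s, 13 and 2 for fragment genotype, 228 and 2198 for Cre against floxed controls, 1207 and 2210 for wild type, 768 and 2234 for added PBS and 608 and 1161 for the transferred lesions. DESeq2 gave 9 for 120000 ILC2s in deficient mice, 3 in wild type, 8 for the difference between them and 29 for 250000 against 120000, where limma gave 0 each. Limma gave 3936 for deficient against competent lesions and 4199 for recipient genotype.

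In fits to the compared groups alone deficient against competent lesions gave 2308 genes, recipient genotype 1677, IL-33 0, fragment genotype 0, Cre against floxed controls 36, wild type 31, added PBS 0, 250000 against 120000 ILC2s 2 and the transferred lesions 3. In no comparison did replicate numbers pair the libraries of all groups: of same-numbered pairs 6 of 24 correlated above 0.1 for deficient against competent lesions and 10 of 24 for recipient genotype. With the replicate number as a block as well, deficient against competent lesions gave 1295, recipient genotype 1154, IL-33 0, fragment genotype 0, Cre against floxed controls 2, wild type 2, added PBS 0 and the transferred lesions 0. Against the fit to the same groups, the block moved by over 1.5 times the counts for deficient against competent lesions, Cre against floxed controls, wild type, 250000 against 120000 ILC2s (to 0) and the transferred lesions, and no other. No label states that replicate numbers pair libraries. Same-numbered libraries correlated between the IL-33 group and the group given 250000 ILC2s, which both enter the difference between 250000 and 120000 ILC2s. With the block its stroma and blood lists were not called. In a fit to both groups alone no gene passed edgeR's test without or with the replicate number as a block (789 and 1027 at an unadjusted p of 0.05).

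Against Cre controls alone, deficient lesions gave 813 genes. The group with added PBS in place of the IL-33 group gave 5 against PBS. Recipient genotype gave 861 in Cre fragments and 964 in deficient fragments, and fragment genotype 10 in deficient recipients. Both gave 214 in the transferred lesions alone, where they change together. With an estimated correlation 2 of 111 list calls over 12 comparisons held, as did 2 of 5 calls of gene sets from another comparison.

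Signs changed for the endometrial stroma list with added PBS (camera adjusted p = 0.0192 with muscle and epithelium scores, 0.0214 with the liver score as well). With the group with added PBS in place of the IL-33 group, the epithelium list changed sign for IL-33 against PBS (5.8e-06) and the proliferation list for 120000 ILC2s in deficient mice (0.00053). With the IL-33 group in place of added PBS, the epithelium (7.7e-09) and proliferation lists (0.0035) changed sign for 250000 ILC2s. In a fit to these 2 groups so did they (6.19e-10 and 0.0073) and the B cell list (0.032), and with the replicate number as a block too (9.65e-16, 5.3e-05 and 0.015). With 1 control for both transfers the epithelium (7.05e-12) and estrogen-response lists (0.00157) changed sign for 250000 against 120000 ILC2s. In deficient fragments alone Cd4 (−0.15), Cd8a (−1.79) and Cd8b1 (−1.15) changed sign by recipient genotype. Leaving out each replicate moved Ehhadh in wild type from −0.46 (without replicate 4 of the wild type, a liver library) to 3.98 (without replicate 3 of the Cre controls, another).

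Leaving out each replicate in turn gave 698 to 2462 genes for deficient against competent lesions, 1602 to 2446 for recipient genotype, 0 to 7 for fragment genotype, 54 to 244 for the transferred lesions and 0 to 4 for IL-33. It gave 45 to 70 for Cre against floxed controls, 87 to 979 for wild type and 0 to 423 for added PBS. For 120000 ILC2s it gave 0 to 1 in deficient mice, where 1 library can be left and is assumed to vary like the other groups, and 0 to 2 in wild type. For 250000 ILC2s and both differences between transfers it gave 0 to 0.

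Among splits of these libraries with the same group sizes, only the real split gave as many genes for deficient against competent lesions (2329, highest other 1583, 1 of 100). The same held for recipient genotype (2403, no other reaching the 214 of the transferred lesions, 1 of 100), Cre against floxed controls (70, highest other 24, 1 of 35) and added PBS (3, 0, 1 of 35). This bounds chance at 1 in 100 or 1 in 35 only, and without 1 replicate the first count fell to 698 and the last to 0. Other splits gave as many for IL-33 (2, highest other 3, 2 of 35), the transferred lesions (214, 291, 2 of 35), wild type (563, 1410, 13 of 100) and fragment genotype (1, 796, 11 of 100). The splits test nothing for 250000 ILC2s (highest other 2) and 120000 ILC2s in wild type (highest other 2805), since with 0 genes called each of the 35 splits gives as many. The high other counts for fragment genotype and 120000 ILC2s in wild type point to structure beyond these groups.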

Other observations

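The clock gene list and all tests on it, and the tests on chromosome 12, were chosen after the results were seen, except that the test of wild-type IL-33 against deficient PBS lesions was set before its values were seen. The genes named next are members of the fixed lists outside the naming rule, were chosen after their values were seen, and were not run under the alternatives for these comparisons. The lectin gene Mgl2, of the type 2 response list, was lower in deficient lesions, at 14.8 ± 6.53 CPM against 53.8 ± 20 in wild type, 61.8 ± 23.6 in floxed controls and 81.7 ± 41.6 in Cre controls (n = 4 each; −2.13 ± 0.51, adjusted p = 0.00649 by edgeR). Of the same list Pdcd1lg2, which encodes the PD-1 ligand PD-L2, was at −2.11 ± 0.60 (adjusted p = 0.0215) and the chemokine gene Ccl22 at −1.34 ± 0.39 (0.0251). By recipient genotype Mgl2 was at −2.29 ± 0.40 (adjusted p = 0.000403) and Pdcd1lg2 at −2.19 ± 0.47 (0.00268), while Ccl22 did not pass (−0.93 ± 0.32, 0.0509).

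Il1b, Ptgs2 and Csf3 were the 3 members of the type 17 and acute inflammation list that were higher in deficient lesions, while the list of 11 measured genes was not called (camera adjusted p = 0.261). Il1b was at 1.22 ± 0.40 (adjusted p = 0.0456 by edgeR), Ptgs2, the gene of cyclooxygenase-2, at 1.24 ± 0.37 (0.0269) and Csf3 at 2.55 ± 0.81 (0.0383), the last with deficient libraries from 0.534 to 13.0 CPM. By recipient genotype Il1b passed (1.11 ± 0.37, adjusted p = 0.0477) and Ptgs2 (0.95 ± 0.34, 0.0659) and Csf3 (1.93 ± 0.80, 0.119) did not.

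Circadian clock genes differed between several groups. Dbp, an output gene of the clock, averaged 95 ± 22.1 CPM in floxed controls, 45.2 ± 7.13 in Cre controls, 25.4 ± 7.20 in wild type and 11.8 ± 2.84 in Cre fragments in deficient recipients (n = 4 each), and by recipient genotype Dbp (−0.99 ± 0.19, adjusted p = 0.00119 by edgeR), Per3 (−0.88 ± 0.13, 5.68e-05) and Hlf (−1.70 ± 0.35, 0.00185) were lower in deficient recipients. The tables argue against tissue mixture as the cause of the Arntl difference with added PBS, which was 0.95 ± 0.16 (adjusted p = 0.00902) and 0.92 ± 0.18 with muscle, epithelium and liver scores as covariates, where the call ended (adjusted p = 0.245) as the standard error grew. Over the 11 group means the score of Arntl, Npas2, Clock and Cry1 ran against that of 10 genes including Dbp and the Per genes (Pearson r = −0.72, permutation p = 0.0123; Spearman rho = −0.70, permutation p = 0.0209; 1 relation tested), and r was −0.53 without the floxed controls and the group with added PBS. Collection at different times of day may give such opposed scores, but it cannot be told apart from an effect of genotype or treatment, since no time is labelled and groups and times would coincide.

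Of 66 genes with a unique position that differed between Cre and floxed controls, 23 lay on chromosome 12 (34.8% against 4.22% of tested genes, Fisher's exact p = 1.14e-15), and 18 of them within 20 Mb of Id2. Protein-coding genes alone were enriched there too (6 of 34, Fisher's exact p = 0.00091). This does not decide whether reads shared between near-identical copies are a cause. Protein-coding genes can have such copies, and Fisher's test treats neighbouring genes as independent. Chromosome 12 sequence from another strain, carried with the floxed Id2 allele, may account for these genes: in wild-type IL-33 against deficient PBS lesions, which share no library with these controls, 23 of 23 had the same sign and 20 passed, and between wild type and Cre controls none of the 23 passed. By fragment genotype, where a segment carried by the fragment would appear, 22 of the 23 had the floxed line's sign but none passed (median 0.80), while by recipient genotype all 23 passed (1.72), and in the transferred lesions alone 21 ran with the recipient and 7 passed. Why these genes ran with the recipient stays open, recipient cells in the lesions included, as does another difference between the lines, since 40 of the 43 genes elsewhere also had the same sign (93.0%, against 53.6% of all genes) and 25 passed.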
